A study of Methylorubrum extorquens with 4 samples.

How the data were processed

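RNA of *Methylorubrum extorquens* strain AM1 grown on ethylamine was compared with RNA of succinate-grown cells on 4 Agilent 2-colour oligonucleotide arrays, each of which held both conditions. Per the labels, cells were grown in batch at 28 °C in mineral salts medium with 40 mM succinate or 20 mM ethylamine. For every array the labels also list tetracycline at 10 µg/ml, kanamycin at 50 µg/ml and rifamycin at 50 µg/ml. They give the 4 arrays as biological replicates. On replicates 1 to 3 the succinate RNA carried dye A555 (green) and the ethylamine RNA dye A647 (red), and on replicate 4 the dyes were swapped. Replicates 1 and 2 were on one array design and scanned on one day, and replicates 3 and 4 on another design scanned on another day. The labels number the RNA pairs S1, S2, S1B and S2B for replicates 1 to 4. They do not say whether S1 and S1B, or S2 and S2B, came from one culture or extract.

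The authors deposited 1 scanner file per array and a value table for each array design. Per the file headers, the spots were read with Agilent Feature Extraction 10.1.1.1 for replicates 1 and 2 and 10.5.1.1 for replicates 3 and 4. The deposited intensity columns hold the mean brightness of each spot and the median of its local background, both without correction, and a processed intensity that the software had background-subtracted and dye-normalized. The deposited log10 column is the log10 ratio of processed red over processed green signal. The deposited value tables hold log2 ratios: set against the scanner files, their values lay on the software's ratio of red over green turned to log2, with no further centring and with replicate 4 not turned. Their column medians were -0.06, -0.04, 0.02 and -0.05 for replicates 1 to 4. A genome build and annotation are not given in the sources used here. Gene models, symbols and products are those of the array files, and positions are on the numbered contigs in them. Overlapping gene models were counted as separate genes. The reference gene table at hand is of strain DM4, and 0 of the 7460 array identifiers occurred in it, so no name was taken from it.

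From the mean signals and local background medians, the background was corrected with normexp (offset 50), and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The normexp offset shrinks ratios of dim genes towards 0. The log2 ratio was turned to ethylamine over succinate on all arrays. Outlier spots were left out (12 to 74 per array), spots of a probe were averaged, and then probes of a gene. There were 7460 genes on both designs. A gene was kept if a probe was well above background in either channel on at least 2 arrays, which left 7239 genes with a value on at least 2 arrays, 7164 of them on all 4. Of the 315 genes with more than 1 probe, 12 had probes that differed by more than 1 in mean log2 ratio, and 1 had probes beyond 0.5 in opposite directions. The SDs given for genes do not include differences between probes. No spot was saturated, and every gene called was well above background in both channels on at least 1 array.

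The mean log2 ratio of each gene was tested against 0 with lmFit and eBayes of limma, and p-values were adjusted by Benjamini-Hochberg over all genes tested. Genes at an adjusted p under 0.05 were called. Unless an alternative is named beside it, an adjusted p given for a gene comes from this fit with n = 4 arrays, and errors are SDs over the 4 arrays. The p-values measure the spread between these arrays, which are fewer than 4 independent samples if arrays of one S number share a culture. The number of arrays limits the precision.

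The 24 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists, then with an estimated correlation and with fry. List members were also counted after an adjustment over the list alone. The rule was to use products only for a list with fewer than 3 symbols matched. Because 189 of the 7460 genes carry a symbol and 4488 a product text, product words were also used for other lists, the TCA cycle and succinate uptake lists among them. These words were chosen after the annotation was read and before any ratio was seen, apart from 1 exclusion (isopropylmalate dehydrogenases, caught by the words for the TCA cycle) made after. Named genes are the 12 highest and the 12 lowest mean log2 ratios among genes called with 1 sign on all arrays, all members of the ethylmalonyl-CoA pathway and serine cycle lists, the 3 members of smallest p of every other list, and the single highest and lowest gene without a name. A bare "hypothetical protein" was counted as no name, a choice made after the values were seen. Other genes that are named were chosen after their values were seen, as said where they stand.

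The alternatives were no background correction, an offset of 0, median centring in place of loess, the software's own ratio, the deposited value tables, other filters on dim probes, a dye term, replicate 4 with its sign not turned, the array design as a block and each design alone, the S numbers as blocks, channels as separate samples, each replicate left out, a trend with robust shrinkage, the median of probes, and the estimated correlation. Chosen after seeing the data were the arrays of an S number averaged, the design as a fixed term, lists by symbol alone, 1 gene model per locus in a list (the longer of overlapping models), and cameraPR without a block. In fits with a random block, lists were tested on the moderated statistics of the genes (cameraPR), so those list results differ from the reported ones in the list test as well as in the block.

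The steps were tested on simulated data for this comparison, with 7240 genes and known changes put into the scanner signals. The test called 20 of 48 genes changed by 0.5 on the log2 scale, 47 of 48 changed by 1, 49 of 49 changed by 2 and 48 of 48 changed by 3. Their median fitted sizes were 0.38, 0.81, 1.54 and 2.34, so ratios of every size, small and large, were understated. A planted list added 14 called genes of 15. Of 182 calls in all, 4 were unchanged genes. The simulated arrays varied independently of each other, and most simulated genes were unchanged. The simulation therefore does not show the error rate if arrays share a culture, or where as many genes change as were called here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.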

Results

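*Methylorubrum extorquens* AM1 is a facultative methylotroph, a bacterium that grows on C1 compounds such as methanol and methylamine and also on larger molecules such as succinate, a C4 acid, and ethylamine, a C2 amine. Transcript levels of cells grown on ethylamine were compared with those of succinate-grown cells on 4 2-colour arrays, 1 per biological replicate, with the dyes swapped on replicate 4. The share of spots well above background ran from 88.2% (green channel, replicate 1) to 97.8% (red channel, replicate 4). Median green signals were 120, 136, 674 and 364 and median red signals 197, 235, 920 and 1253 for replicates 1 to 4, over median local backgrounds of 16.0 to 20.0 (green) and 40.0 to 49.0 (red). Ratios are given as log2 of ethylamine over succinate, mean ± SD over n = 4 arrays unless said otherwise, and "rose" and "fell" are used for an adjusted p under 0.05.

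On ethylamine, all 11 measured genes of the methylamine dehydrogenase (mau) cluster rose, and 6 of them were among the 12 highest named genes of the whole array. *mauF* (RMQ09321) rose by 5.55 ± 0.39 (46.8-fold, adjusted p = 5.2e-05) and *mauB* (RMQ00025), which encodes the large subunit of the enzyme that oxidizes primary amines to aldehydes in the periplasm, by 5.18 ± 0.54 (36.3-fold). *mauA* (RMQ09318), the small subunit, rose by 4.42 ± 0.50, *mauC* (RMQ00042), the electron acceptor amicyanin, by 4.06 ± 0.54, and the maturation genes *mauD* (RMQ09319) and *mauE* (RMQ09320) by 4.60 ± 0.55 and 4.67 ± 0.49. At the other end, a C4-dicarboxylate transport protein (RMQ02662), of a family of carriers that take up succinate, fumarate and malate, fell by 5.98 with an SD of 0.06 (63.0-fold, adjusted p = 2.5e-06), the lowest ratio measured. Over 7239 genes tested, 1721 rose and 1783 fell, and 946 of these changed at least 2-fold, 460 upwards and 486 downwards. Normalization sets the ratios of each array around 0 (median of all genes 0.00), so the near-even split is not a result of its own. Whether rises and falls balance in the cells was not tested. Median centring in place of loess gave 1278 higher and 985 lower. Of the called genes, 3474 of 3504 had the same sign on all 4 arrays.

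The array design, which went with the scan day, was followed as a batch. With the design as a random block (estimated correlation -0.17), 1852 genes were higher and 1950 lower, and with the design as a fixed term, chosen after seeing the data, 1645 and 1723. With the S numbers as a random block (estimated correlation 0.20) there were 1576 and 1619. Within the design of replicates 1 and 2 alone the counts were 749 and 851, and within that of replicates 3 and 4 alone 938 and 1023. Arrays with the same S number in the labels may share a culture. When they were averaged to 1 value per number, an alternative chosen after seeing the data, 1063 genes were higher and 1102 lower, 2156 of which were also called with the same sign from the 4 arrays.

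Of the 24 gene lists, 11 changed as a group in the camera test with a preset correlation of 0.01, 6 upwards and 5 downwards. The subjects and symbols of the lists were fixed beforehand, but many members came from product words chosen after the annotation was read. With a correlation estimated from these 4 arrays, 0 of the 24 passed, and 0 had an unadjusted p under 0.05. Each list's adjusted p with an estimated correlation is given beside its call. That p does not measure gene correlation alone, since with an estimate camera also allows for there being only 4 arrays. The ethylmalonyl-CoA list had an estimated correlation of -0.05, below the preset 0.01, yet its adjusted p went from 0.014 to 0.49. For that list the loss cannot be put down to correlation between genes. Other estimates lay far above the preset, with 0.96 for methylamine dehydrogenase, 0.72 for ribosomal proteins and 0.59 for flagella and chemotaxis. The camera p of these lists at the preset allowed for far less correlation than was estimated and is likely too small. For them the p with an estimate does not separate correlation from the small number of arrays. Fry asks whether the genes of a list move one way on balance without comparing them with other genes. It passed 18 lists, but not the ribosomal list that camera called downwards (fry adjusted p = 0.075). For change in either direction it passed all 24. With 3504 of the 7239 genes tested called, that result does not set any list apart.

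**Figure D1:**
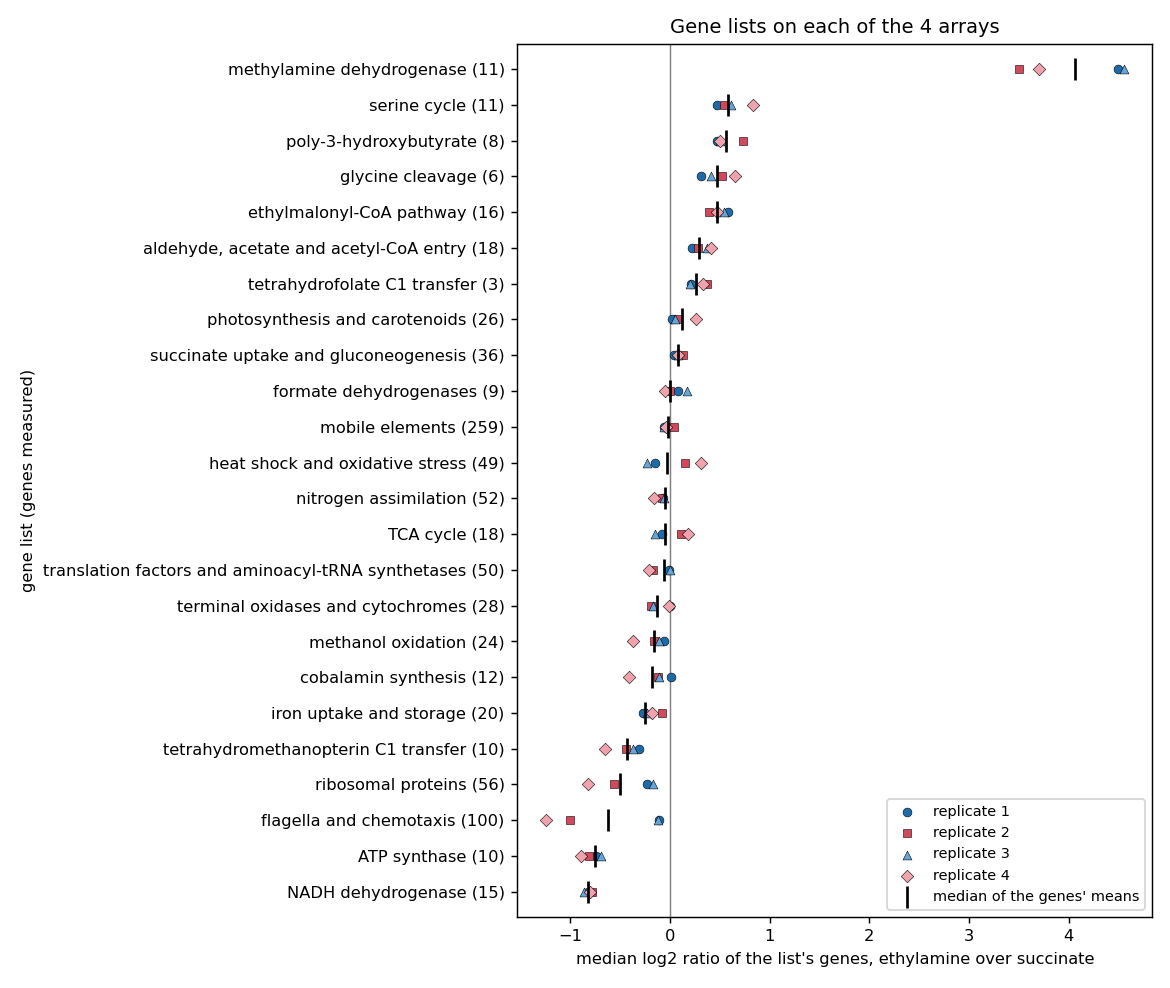
Median log2 ratio of ethylamine over succinate for the 24 gene lists (horizontal axis) on each of the 4 arrays (coloured symbols), with the median over the list of the genes' means as a black bar and the number of genes measured in brackets. The methylamine dehydrogenase list lies at 3.50 to 4.55 on the 4 arrays, and the flagella and chemotaxis list near 0 on replicates 1 and 3 (-0.11 and -0.12) and far lower on replicates 2 and 4 (-1.24 on replicate 4).

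The methylamine dehydrogenase list had a median log2 ratio of 4.06 ± 0.54 (camera adjusted p = 4.4e-08, adjusted p = 0.50 with an estimated correlation), and adjusted over the list alone all 11 members again rose. The genes lie on contig 1477 of the array files, in a run of 12 genes between positions 836 and 10332 that also holds a regulator (RMQ00220). In the list for aldehyde, acetate and acetyl-CoA entry, 11 of 18 measured genes rose, 2 fell and 5 did not pass, with the same 11 and 2 counts when adjusted over the list alone. An aldehyde dehydrogenase (RMQ03452) rose by 3.80 ± 0.09 (14.0-fold, adjusted p = 2.3e-05), and an acetyl-coenzyme A synthetase (RMQ07389), which makes acetyl-CoA from acetate, rose by 1.77 ± 0.22 (3.41-fold). A large subunit of a membrane-bound aldehyde dehydrogenase (RMQ12099) fell by 0.85 with an SD of 0.13. As a group the list stood at a median of 0.29 ± 0.09 (camera adjusted p = 0.020, adjusted p = 0.50 with an estimated correlation). Its call was lost in the design of replicates 1 and 2 alone (median 0.24, adjusted p = 0.082). The median was higher under other processing, with 0.57 at a normexp offset of 0 and 0.68 with the software's or the deposited ratios.

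This bacterium has no isocitrate lyase and turns acetyl-CoA into glyoxylate through the ethylmalonyl-CoA pathway. Of its 16 measured gene models, 12 rose, 3 fell and 1 did not pass, and the counts were the same when adjusted over the list alone. The methylmalonyl-CoA mutase genes *mcmA* (RMQ12744, 1.29 ± 0.34, and RMQ00448, 1.14 ± 0.26, overlapping models of 1 locus) and *mcmB* (RMQ12432, 0.95 ± 0.33), *meaA* (RMQ00015, 1.26 ± 0.08), annotated elsewhere as ethylmalonyl-CoA mutase, the crotonase *croR* (RMQ01208, 1.16 ± 0.17), *ibd2* (RMQ04586, 1.13 ± 0.09) and *ccr* (RMQ09548, 1.09 ± 0.19), crotonyl-CoA carboxylase/reductase, rose the most. *meaD* (RMQ07639) rose by 0.56 ± 0.21, and *phaB* (RMQ03831, 0.37 ± 0.21), *meaB* (RMQ07583, 0.29 ± 0.14), *pccA* (RMQ11711, 0.29 ± 0.09) and *phaA* (RMQ11702, 0.24 ± 0.09) rose less. The 3 that fell were *meaC* (RMQ01146, -0.61 ± 0.18), the epimerase gene *epm* (RMQ05448, -0.52 ± 0.08) and *mcl* (RMQ06958, -0.50 ± 0.26), malyl-CoA lyase, and *pccB* (RMQ09543) was at -0.12 ± 0.23 (adjusted p = 0.39). Over the pathway the median was 0.47 ± 0.08, a 1.38-fold difference (camera adjusted p = 0.014, adjusted p = 0.49 with an estimated correlation). With the longer *mcmA* model alone, an alternative chosen after seeing the data, the median was 0.37 (adjusted p = 0.022). The full list stood at 0.45 in the design of replicates 1 and 2 (adjusted p = 0.010) and 0.49 in that of replicates 3 and 4 (adjusted p = 0.023). The calls of *phaA*, *pccA*, *meaB*, *phaB* and *mcl* were each lost without at least 1 of the arrays. With median centring in place of loess *meaC*, *epm* and *mcl* no longer passed (adjusted p = 0.21, 0.31 and 0.34), nor did *meaB*, *phaA* and *pccA* (adjusted p = 0.10, 0.062 and 0.066), and *pccB* turned to 0.12.

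In the serine cycle, which assimilates C1 units and regenerates glyoxylate, 6 of 11 measured gene models rose, 1 fell (*mcl*, shared with the ethylmalonyl-CoA list) and 4 did not pass, with the same counts when adjusted over the list alone. The malate thiokinase genes *mtkA* (RMQ06989) and *mtkB* (RMQ06988) rose by 1.60 ± 0.14 (3.03-fold) and 1.20 ± 0.17, glycerate kinase *gck* (RMQ11866) by 0.96 ± 0.14, malate dehydrogenase *mdh* (RMQ06488) by 0.95 ± 0.23, phosphoenolpyruvate carboxylase *ppc* (RMQ12876) by 0.64 ± 0.16 and serine-glyoxylate aminotransferase *sga* (RMQ12088) by 0.58 ± 0.12. Single probes of *gck* ranged from 0.51 to 1.45. Hydroxypyruvate reductase *hpr* (RMQ03312, 0.39 ± 0.49, adjusted p = 0.14), the enolase gene *eno* (overlapping models RMQ04824, 0.17 ± 0.08, and RMQ10950, 0.12 ± 0.03) and *glyA* (RMQ07918, -0.19 ± 0.24) did not pass. With median centring *hpr* passed (0.62, adjusted p = 0.024) and *glyA* turned to 0.16. Over the serine cycle the median was 0.58 ± 0.15 (camera adjusted p = 0.014, adjusted p = 0.50 with an estimated correlation). In the glycine cleavage list, 4 of 6 genes rose and 2 did not pass, also when adjusted over the list alone, with genes annotated as aminomethyltransferase at 0.77 ± 0.13 (RMQ10636), 0.74 ± 0.15 (RMQ04395) and 0.67 ± 0.26 (RMQ03822). Its median was 0.47 ± 0.15 (camera adjusted p = 0.029, adjusted p = 0.50 with an estimated correlation). This call was lost in the design of replicates 1 and 2 alone (adjusted p = 0.15), with channels as separate samples (adjusted p = 0.12), and without replicate 4 (median 0.42, adjusted p = 0.078). It did not pass with the software's ratio (adjusted p = 0.069), the deposited ratios (adjusted p = 0.067) and a normexp offset of 0 (adjusted p = 0.057). It was also lost with either random block, the design or the S numbers (adjusted p = 0.091 for both), for which lists were tested with cameraPR, and with cameraPR without a block (adjusted p = 0.094). With median centring the list passed at a higher median of 0.73 (adjusted p = 0.030). Of 8 genes for poly-3-hydroxybutyrate, a carbon store made from acetyl-CoA, 7 rose and 1 fell, also when adjusted over the list alone. Among those that rose are *phaA* and *phaB*, which are shared with the ethylmalonyl-CoA list, so the 2 lists are not independent. The depolymerase genes *depB* (RMQ07801) and *depA* (RMQ01094) rose by 1.84 ± 0.53 and 0.76 ± 0.02 and the hydroxybutyrate dehydrogenase gene *hbd* (RMQ09145) by 0.56 ± 0.21. Together these 8 genes had a median of 0.56 ± 0.12 (camera adjusted p = 0.020, adjusted p = 0.49 with an estimated correlation). The adjusted p was 0.062 with the design and 0.066 with the S numbers as a random block, and 0.068 with cameraPR without a block. With median centring the median was 0.90 (adjusted p = 0.015).

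**Figure D2:**
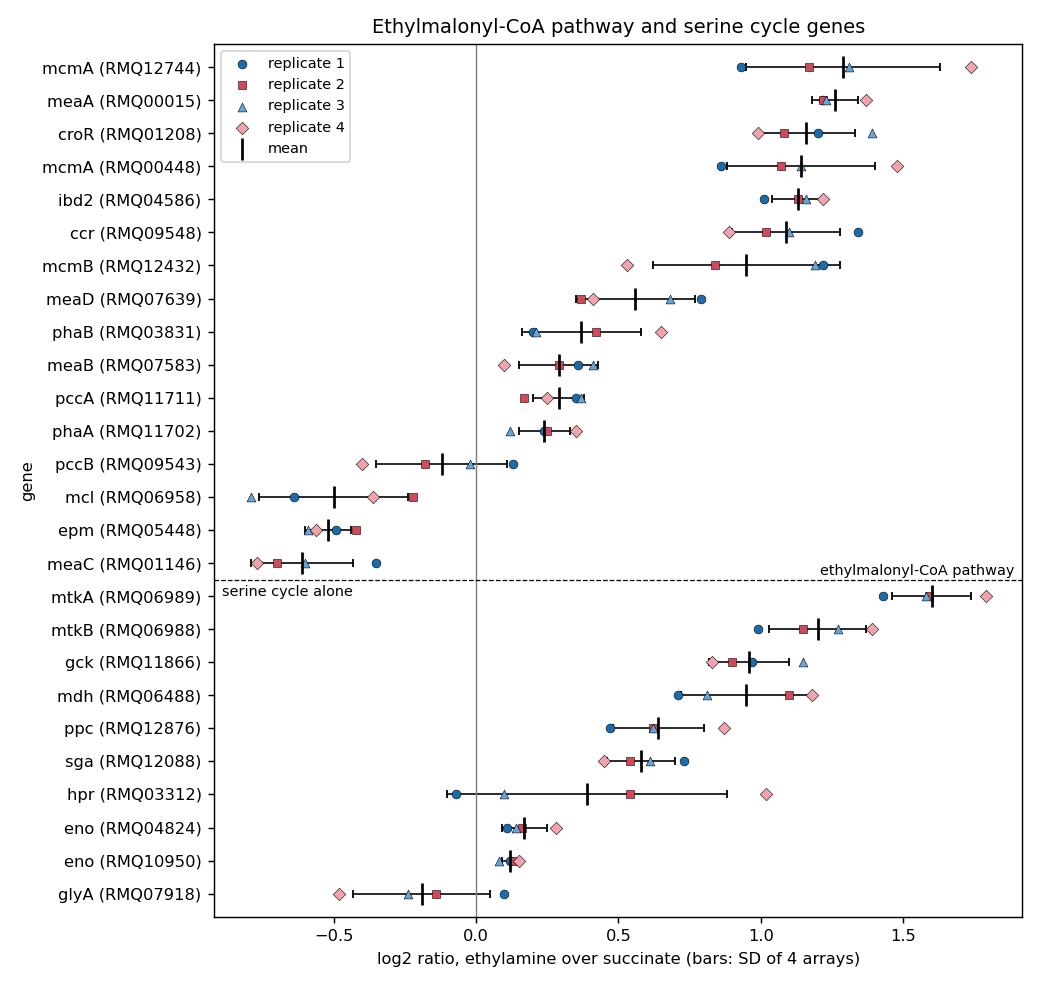
Log2 ratio of ethylamine over succinate (horizontal axis) of each measured gene of the ethylmalonyl-CoA pathway (upper block) and of the serine cycle genes not in that pathway (lower block), with 1 coloured symbol per array, the mean as a black bar and the SD of the 4 arrays as error bars. Means run from -0.61 (*meaC*) to 1.29 (*mcmA*) in the upper block and from -0.19 (*glyA*) to 1.60 (*mtkA*) in the lower one.

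Of 10 genes of the tetrahydromethanopterin pathway, through which formaldehyde is oxidized, 6 fell, 1 rose and 3 did not pass, also when adjusted over the list alone. *dmrA* (RMQ07614) was at -0.65 ± 0.06, *mch* (RMQ05670) at -0.55 ± 0.08 and *fhcD* (RMQ08757) at -0.42 ± 0.11. The list's median was -0.43 ± 0.15 (camera adjusted p = 0.025, adjusted p = 0.50 with an estimated correlation). This call was lost with the design (adjusted p = 0.095) or the S numbers (adjusted p = 0.099) as a random block and with cameraPR without a block (adjusted p = 0.094), in the design of replicates 3 and 4 alone (adjusted p = 0.061) and with median centring in place of loess (median -0.21, adjusted p = 0.57), under which the calls of *mch* and *fhcD* were lost too (adjusted p = 0.31 and 0.37). Of the 3 tetrahydrofolate genes, *fch* (RMQ06990) rose by 0.81 ± 0.15 and *mtdA* (RMQ03311) by 0.26 ± 0.11, and *ftfL* (RMQ05969, 0.17 ± 0.07) passed only when adjusted over the list alone, which gave 3 of 3. The list as a whole did not pass in camera (median 0.26 ± 0.09, adjusted p = 0.10) but passed upwards in fry (adjusted p = 0.0061). The call of *mtdA* was lost without any 1 of the arrays and with median centring (adjusted p = 0.066). Of 9 formate dehydrogenase genes, 4 rose and 2 fell, also when adjusted over the list alone. *fdh1B* (RMQ07911), of the tungsten-dependent enzyme, rose by 1.86 ± 0.20, and *fdh2B* (RMQ12670) and *fdh2C* (RMQ04236), of the molybdenum-dependent enzyme, by 0.85 ± 0.17 and 0.69 ± 0.12. Single probes of *fdh2B* ranged from 0.48 to 1.56 and those of *fdh2C* from 0.41 to 1.09. The formate dehydrogenase list had a median of 0.00 ± 0.10 and a mean of 0.31 (camera adjusted p = 0.48, fry upwards with adjusted p = 0.0066). In the methanol oxidation list, 9 of 24 genes rose and 12 fell (10 and 12 adjusted over the list alone). *mxaW* (RMQ06367) rose by 2.25 ± 0.31, while *mxaL* (RMQ05267, -1.02 ± 0.08) and *mxaD* (RMQ05268, -1.22 ± 0.15), whose products serve calcium insertion into methanol dehydrogenase in the array annotation, fell. Over the 24 genes the median was -0.16 ± 0.14 (camera adjusted p = 0.75, fry downwards with adjusted p = 0.025), -0.09 without replicate 4 and 0.02 with median centring.

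For succinate uptake and gluconeogenesis, 9 of 36 genes rose, 9 fell and 18 did not pass, with the same counts adjusted over the list alone. Beside the C4-dicarboxylate transport protein that fell, a C4-dicarboxylate-binding protein (RMQ02802) and the small subunit of a C4-dicarboxylate transporter (RMQ05167) rose by 1.53 ± 0.14 and 1.07 ± 0.09. The list's median was 0.08 ± 0.04 and its mean -0.10, so that the camera direction (up, adjusted p = 0.78) and fry's (down, adjusted p = 0.0014) differed. In the TCA cycle, 8 of 18 genes rose and 6 fell (8 and 7 adjusted over the list alone). The list had a median of -0.05 ± 0.16 and a mean of -0.29 (camera adjusted p = 0.78, fry downwards with adjusted p = 0.0077). The median's sign was not stable: it was 0.26 with median centring and -0.11 to 0.02 when 1 replicate was left out. Genes annotated as fumarate hydratase fell by 3.35 with an SD of 0.17 (RMQ10718, 10.2-fold) and by 3.24 with an SD of 0.14 (RMQ11545), and the succinate dehydrogenase model *sdhA, sdhB* (RMQ12137) by 1.13 with an SD of 0.13. Single probes of the *sdhA, sdhB* model ranged from -1.44 to -0.50. With cameraPR the list passed, both without a block (adjusted p = 0.030) and with the design (0.034) or the S numbers (0.037) as a random block. It did not with the design as a fixed term (adjusted p = 0.76), with the S numbers averaged (adjusted p = 0.80) or with an estimated correlation (adjusted p = 0.96). A malate:quinone oxidoreductase (RMQ05989), which oxidizes malate to oxaloacetate and was not on the list, was at -3.44 ± 0.36 (10.8-fold lower).

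Of 15 genes of the proton-pumping NADH dehydrogenase, 12 fell, 1 rose and 2 did not pass, also when adjusted over the list alone. Chains L (RMQ09623), M (RMQ02676) and G (RMQ12606) were at -1.34 ± 0.10, -1.32 ± 0.06 and -1.15 ± 0.06. Over the 15 genes the median was -0.82 ± 0.03 (camera adjusted p = 1.0e-04, adjusted p = 0.49 with an estimated correlation), and -0.53 with median centring in place of loess (adjusted p = 0.025). Of 10 ATP synthase genes, 9 fell and 1 did not pass, also when adjusted over the list alone, with the epsilon chain (RMQ05614) at -1.31 ± 0.26, a gene named only ATP synthase (RMQ08843) at -0.90 ± 0.09 and the A chain (RMQ08842) at -0.75 ± 0.07. Its median was -0.75 ± 0.09 (camera adjusted p = 4.6e-04, adjusted p = 0.49 with an estimated correlation). With median centring in place of loess it was -0.40 (adjusted p = 0.091), and the A chain no longer passed (adjusted p = 0.24). Of 28 genes for terminal oxidases and cytochromes, 8 rose and 11 fell (9 and 11 adjusted over the list alone), with a median of -0.13 ± 0.10, a mean of 0.12 and an upward direction in camera (adjusted p = 0.92) and fry (adjusted p = 0.0090), against the sign of the median. This median was -0.16 to -0.07 when 1 replicate was left out and 0.17 with median centring. Subunits of cytochrome d ubiquinol oxidase, a quinol oxidase with high affinity for oxygen in other bacteria, rose by 2.12 ± 0.30 (subunit I, RMQ02158), 1.94 ± 0.18 (subunit II, RMQ03604) and 1.69 ± 0.24 (subunit II, RMQ05199).

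Of 100 measured genes for flagella and chemotaxis, 43 fell, 0 rose and 57 did not pass, with the same counts adjusted over the list alone. Flagellins, the subunits of the flagellar filament, were among the lowest genes of the array, at -4.57 ± 0.97 (RMQ06533, 23.8-fold lower), -4.46 ± 0.62 (RMQ07574) and -3.84 ± 0.93 (RMQ07573). Methyl-accepting chemotaxis proteins were at -3.33 ± 0.79 (RMQ05246) and -1.37 ± 0.12 (RMQ08571), and a cheY response regulator (RMQ08384) was at -2.38 ± 0.22. The list's median was -0.62 ± 0.59 (camera adjusted p = 4.4e-08, adjusted p = 0.66 with an estimated correlation). The arrays differed: -0.11 and -0.12 on replicates 1 and 3 (S1 and S1B), and far lower on replicates 2 and 4 (S2 and S2B), with -1.24 on replicate 4 and -0.90 as the median difference of replicate 2 from replicate 1. Of 56 ribosomal protein genes, 31 fell, 1 rose and 24 did not pass (35 fell and 1 rose adjusted over the list alone). S1P (RMQ01212) was at -1.04 ± 0.18, L1E (RMQ11543) at -0.82 ± 0.27 and L3P (RMQ00685) at -0.66 ± 0.21. The ribosomal list had a median of -0.50 ± 0.30 (camera adjusted p = 1.5e-05, adjusted p = 0.72 with an estimated correlation). Fry did not pass this list (adjusted p = 0.075). Its median was -0.23, -0.56, -0.17 and -0.82 on replicates 1 to 4. After median centring it was -0.09 (adjusted p = 0.62), and S1P, L1E and L3P no longer passed (adjusted p = 0.14, 0.33 and 0.64). Of 50 genes for translation factors and aminoacyl-tRNA synthetases, 16 fell and 6 rose, also when adjusted over the list alone (median -0.06 ± 0.11, camera adjusted p = 0.22). That median was -0.12 to -0.05 when 1 replicate was left out and 0.04 with median centring. Initiation factor IF-1 (RMQ05961, -0.97 ± 0.07) and release factor RF-1 (RMQ07383, -0.65 ± 0.15; adjusted p = 0.067 with median centring) fell, and seryl-tRNA synthetase (RMQ05481) rose by 0.82 ± 0.13.

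The lists for stress, nitrogen, iron, pigments, cobalamin and mobile elements did not pass as groups in camera. Fry passed the iron list downwards (adjusted p = 4.7e-04) and the photosynthesis and carotenoid list upwards (adjusted p = 0.014), but not the others. Of 49 genes for heat shock and oxidative stress, 16 rose and 13 fell (16 and 15 adjusted over the list alone), and the median was -0.03 ± 0.25 (camera adjusted p = 0.91), with -0.17 to 0.06 when 1 replicate was left out and 0.13 with median centring. The chaperonin genes GroEL (RMQ02595, -2.72 ± 0.46) and GroES (RMQ06831, -2.23 ± 0.27) and a peroxidase (RMQ07738, -2.17 ± 0.41) fell, and small heat shock proteins RMQ02258 and RMQ03517, chosen after their values were seen, rose by 2.65 ± 0.66 and 2.56 ± 0.56. Of 52 genes for nitrogen assimilation, 12 rose and 15 fell, also when adjusted over the list alone (median -0.05 ± 0.05, camera adjusted p = 0.66). A glutamine synthetase (RMQ07219) rose by 1.91 ± 0.39 and a nitrate reductase (RMQ05669) by 1.05 ± 0.09, while the nitrogen regulatory protein P-II (RMQ08465) was at -1.07 ± 0.12. Of 20 genes for iron uptake and storage, 8 fell and 1 rose, also when adjusted over the list alone (median -0.25 ± 0.08, camera adjusted p = 0.10; -0.14 without replicate 1 and -0.13 without replicate 3), with ferrichrome-iron receptors at -1.87 ± 0.18 (RMQ02870), -1.76 ± 0.26 (RMQ02548) and -0.81 ± 0.17 (RMQ12825). Of 26 genes for photosynthesis and carotenoids, 5 rose and 3 fell (5 and 2 adjusted over the list alone), the phytoene desaturase gene *crtI* (RMQ04999) by 0.99 ± 0.26, a bacteriochlorophyll-geranylgeranyl reductase (RMQ01034) by 0.63 ± 0.12 and a bacteriochlorophyllide synthase (RMQ08070) by 0.57 ± 0.17, with a list median of 0.12 ± 0.11 (camera adjusted p = 0.20) that was 0.05 without replicate 4. Of 12 genes for cobalamin synthesis, 3 rose and 1 fell, also when adjusted over the list alone. A cobalamin synthase (RMQ01360, 0.91 ± 0.08) and a precorrin-2 oxidase (RMQ11787, 0.87 ± 0.15) rose and precorrin-3B C17-methyltransferase (RMQ06304) was at -0.96 ± 0.25. The list's median was -0.18 ± 0.18 (camera adjusted p = 0.88), and -0.10 without replicate 4. Of 259 mobile element genes, 28 rose and 46 fell (23 and 45 adjusted over the list alone), among them transposases at -2.72 ± 0.32 (RMQ04182) and -1.16 ± 0.10 (RMQ08825) and a phage tail protein at -1.97 ± 0.23 (RMQ02696), with a median of -0.02 ± 0.05 (camera adjusted p = 0.45).

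Several of the largest changes lay outside the lists. AraC family regulators, which switch transcription in response to small molecules, rose by 3.71 ± 0.24 (RMQ07949, 13.1-fold) and 3.62 ± 0.39 (RMQ07760), a cytochrome c (RMQ07946) by 3.65 ± 0.41, ornithine decarboxylase (RMQ07250) by 3.44 ± 0.46 and ornithine cyclodeaminase (RMQ09527) by 3.40 ± 0.54. An acyl-CoA synthetase (RMQ08307) and a thioesterase (RMQ08306) were at -4.28 ± 0.58 and -4.28 ± 0.51. A type 4 prepilin peptidase (RMQ06287), which processes pilin-like proteins, was at -3.83 ± 0.44 and a protein named for sporulation protein EshA (RMQ09688) at -3.37 ± 0.13. Of the 3504 genes called, 1399 had neither a symbol nor a product name, 730 of them higher and 669 lower. The highest of them, RMQ02553, rose by 5.03 ± 0.39 (32.8-fold), and the lowest, RMQ06004, was at -5.08 ± 0.85 (33.9-fold lower). RMQ02553, RMQ07946 and RMQ07949 lie in a run of 12 neighbouring genes on contig 1567 that rose at least 2-fold, between positions 2946 and 12687, as long as the run of 12 that holds the mau genes. These runs were looked for after the values were seen.

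**Figure D3:**
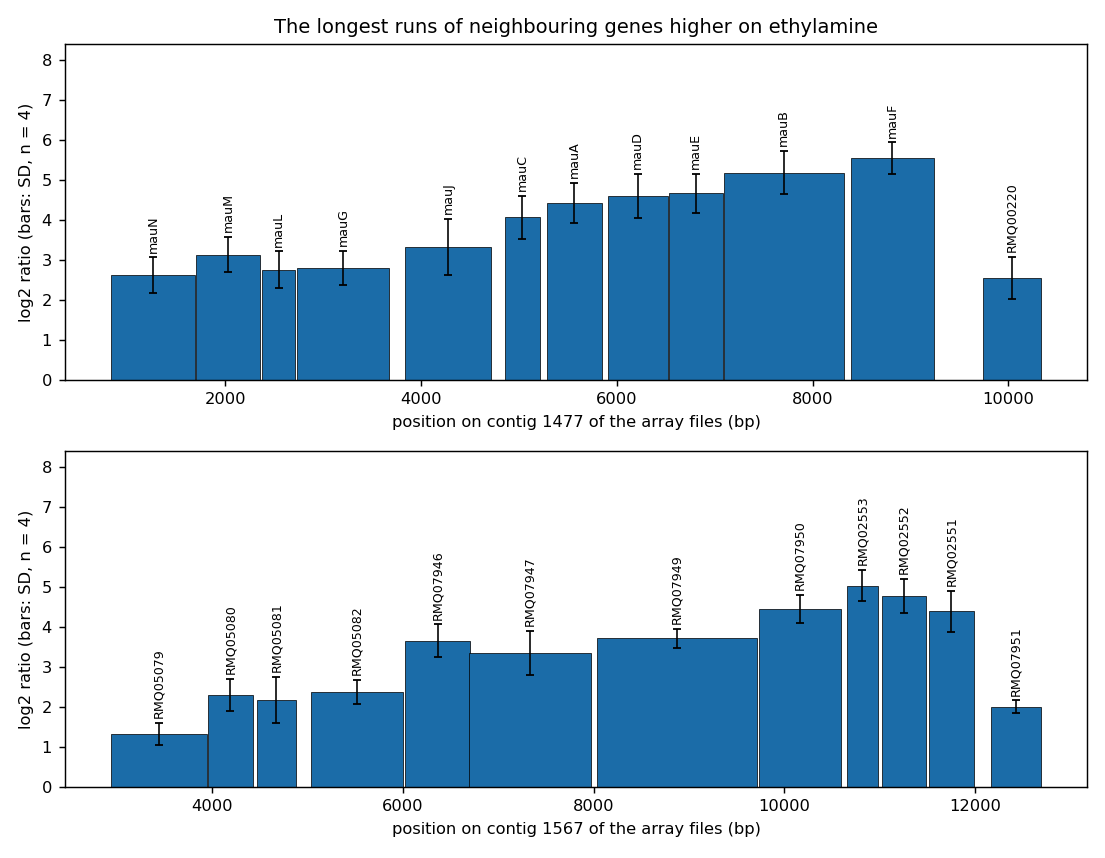
Log2 ratio of ethylamine over succinate (vertical axis, bars with the SD of 4 arrays) of the genes in the longest runs of neighbouring genes that rose at least 2-fold, drawn to scale along contigs 1477 (upper panel) and 1567 (lower panel) of the array files. In the upper panel the 11 mau genes and a regulator (RMQ00220) lie between 2.55 and 5.55, and in the lower panel 12 genes lie between 1.32 and 5.03.

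The arrays resembled each other across genes, which are not independent replicates. Over the 6 pairs of arrays Pearson's r of the turned log2 ratios was 0.80 to 0.94 with a median of 0.88. The highest values, 0.94 for replicates 1 and 3 and 0.93 for replicates 2 and 4, belonged to the pairs with the same S number on different designs. Replicates 1 and 2, on the same design with the same dyes, had r = 0.89, and replicates 3 and 4, with the dyes swapped between them, 0.85. Without turning replicate 4, its correlations with replicates 1, 2 and 3 were -0.80, -0.93 and -0.85.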

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

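The test over sign patterns of the arrays was chosen before the results were seen, and the tests of dye and array design that follow were chosen after.

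Among 134 named genes and list medians, 6 had 1 of the 4 arrays far from the others, as chance does in about 1 of 20. For *meaA* (RMQ00015) replicate 4 lay at 1.37 and the others at 1.22 to 1.23. For *fch* (RMQ06990) replicate 4 lay at 1.02 and the others at 0.71 to 0.76. For *mxaL* (RMQ05267) replicate 4 lay at -1.13 and the others were higher, up to -0.97. For the ATP synthase gene RMQ08843 replicate 4 lay at -0.77 and the others at -0.96 to -0.93. For cytochrome d ubiquinol oxidase subunit II (RMQ05199) replicate 3 lay at 2.05 and the others at 1.52 to 1.60. The median of the poly-3-hydroxybutyrate list lay at 0.73 on replicate 2 and at 0.47 to 0.50 on the others.

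The breadth of the change, 3504 of 7239 genes called, was set against technical explanations. A dye bias would turn its sign on replicate 4: of the 3336 genes called from replicates 1 to 3 alone, 95.5% had the same sign on replicate 4, where the dyes were swapped. An effect of 1 array design or scan day would be missing on the other: of the genes called from either design alone, at least 99.5% had the same sign on the other. The 8 sign patterns of 4 arrays are too few for a share under 0.05. The real pattern called 3504 genes and the highest of the others 0, with at most 147 at an unadjusted p under 0.05 (limma). Fits of the other patterns left the ethylamine difference in their error, so their counts of 0 say little about other groupings. The pattern of the S numbers called 0 genes here but 348 in a fit that also held the mean ratio. Growth on ethylamine rather than succinate is the biological difference that the design names, and a hypothesis that stays open beside any other difference between the cultures, such as growth rate or stage, which the labels do not give.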

How the results depend on the processing

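Arrays and spots over background limit these results: 88.2% to 97.8% of spots were well above background, and n is 4. The alternatives with S numbers averaged, the design as a fixed term, lists by symbol alone, 1 gene model per locus and cameraPR without a block were chosen after seeing the data. The cause of a shift was not tested unless said.

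Counts stayed within 1.5 times the reported 1721 higher, 1783 lower and 946 changed at least 2-fold except as follows. Median centring in place of loess gave 985 lower, and median r between arrays fell from 0.88 to 0.80. The software's own ratio gave 1440 genes changed at least 2-fold, and the ratios the authors deposited gave 1439. With fewer arrays or samples per test, the design of replicates 1 and 2 alone gave 749 higher and 851 lower, that of replicates 3 and 4 alone 938 and 1023, and the S numbers averaged 1063 and 1102. With no replicate block, that is with channels as separate samples rather than paired on an array, there were 1048 and 1146. With replicate 4 not turned, 0 genes were higher, 0 lower and 0 changed 2-fold (limma, 136 at an unadjusted p under 0.05), 3 lists changed, and the ethylmalonyl-CoA median was 0.30 (adjusted p = 0.095), since opposite signs cancel. Leaving out 1 replicate gave 1210 to 1662 higher, 1262 to 1674 lower, 855 to 1050 changed at least 2-fold and 10 to 11 lists.

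Of the lists, 11 changed as reported, 18 with fry, 5 of 10 with members by symbol alone (fewer lists tested) and 0 with an estimated correlation (0 at an unadjusted p under 0.05), under which the ethylmalonyl-CoA median of 0.47 had an adjusted p of 0.49. Its median was 0.37 (1 gene model per locus) to 0.68 and its adjusted p 4.7e-04 to 0.037 under every other alternative but the unturned replicate 4. The random blocks and cameraPR without a block each gave 9 lists, so these calls went with the list test and not the block. Among named genes and lists, no call of limma or camera changed sign; fry called succinate uptake downwards against its median of 0.08 and terminal oxidases upwards against -0.13. For the other 23 lists 522 results kept their side of the threshold, 38 called lists lost and 4 gained a call, and 20 uncalled medians near 0 changed sign. For the 110 named genes 2217 results kept their side and 193 lost a call (104 of them with replicate 4 not turned). A further 5 gained a call and 5 uncalled values changed sign. With the S numbers averaged 7 of the 110 lost their call, and with channels as separate samples 12 did.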

Other observations

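The genes and tests in this part were chosen after the results were seen.

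A run of 5 neighbouring genes for sulfate uptake fell on ethylamine, with the sulfate transport genes cysA (RMQ06385) at -1.72 ± 0.20, cysW (RMQ01067) at -1.96 ± 0.31 and cysT (RMQ06384) at -2.57 ± 0.54 (SD, n = 4) and sulfate-binding proteins at -2.58 ± 0.45 (RMQ06383) and -2.17 ± 0.56 (RMQ11938). Alkanesulfonate transport genes fell too: both permease genes were at -1.31 ± 0.31 (RMQ06513) and -1.75 ± 0.51 (RMQ06514) beside a lower binding protein gene (RMQ00894) and an FMN reductase (RMQ12434) at -1.43 ± 0.26. In the run on contig 1567, sulfite dehydrogenase (RMQ07947), which oxidizes sulfite to sulfate, rose by 3.35 ± 0.55 beside a cytochrome c (RMQ07946, 3.65 ± 0.41), a metal-dependent hydrolase (RMQ05082, 2.37 ± 0.30) and another sulfate-binding protein (RMQ05079, 1.32 ± 0.28).

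Other blocks that rose held a cytochrome C550 (RMQ06254, 3.17 ± 0.14) with an alcohol dehydrogenase (RMQ11337, 2.91 ± 0.12) and a periplasmic amino-acid binding protein (RMQ02495, 2.61 ± 0.23), and xanthine dehydrogenase genes (RMQ05169, 2.12 ± 0.67 and RMQ07057, 1.14 ± 0.36). A fixK regulator (RMQ05837, 1.04 ± 0.12), cydC (RMQ01186, 1.07 ± 0.30), a transporter gene needed for cytochrome d oxidase in other bacteria, and a universal stress protein (RMQ02615, 3.15 ± 0.37) also rose together. Blocks that fell held runs of 9 and 5 genes on contig 1568, most of them without a product name, with a coat protein (RMQ01226, -3.06 ± 0.44), a terminase large subunit (RMQ10472, -1.81 ± 0.41) and a portal protein (RMQ02426, -1.65 ± 0.27). A polyketide synthase gene (RMQ08310, -2.38 ± 0.49) and a malonyl-CoA transacylase (RMQ08309, -2.84 ± 0.27) fell beside the acyl-CoA synthetase RMQ08307, and a DNA protection during starvation protein (RMQ07737, -2.86 ± 0.51) and cytochrome b561 (RMQ01923, -1.96 ± 0.24) fell beside the peroxidase RMQ07738. A chemotaxis-like cluster with cheY (RMQ03257, -3.18 ± 0.64), cheW (RMQ09415, -2.03 ± 0.33) and a pili cheA homologue (RMQ09416, -3.02 ± 0.55) fell as well.

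There were 29 runs of at least 4 neighbouring genes that changed at least 2-fold the same way, 12 up and 17 down, with 154 of the 946 genes. Of 1000 shuffled gene orders, 0 gave as many runs, and the most in any was 3, which argues against a gene order unrelated to the change. A candidate explanation is that the genes of a run are transcribed together. In 23 places in these runs neighbouring gene models overlap in position, and signal shared between overlapping models stays open for those.

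The ratio of many genes followed the S number in the labels. Between arrays numbered S2 or S2B and those numbered S1 or S1B, 348 of 7164 genes differed in log2 ratio (limma, adjusted p under 0.05), 144 higher and 204 lower, 58 of the latter from the flagella and chemotaxis list. Between array designs 0 did, with 431 at an unadjusted p under 0.05. That fit held no term for the S number, so differences between the numbers widened its error. The count of 0 therefore does not show that the designs do not differ. The list's median difference between numbers was -1.03 (quartiles -1.30 and -0.39; camera adjusted p = 3.4e-33, adjusted p = 0.54 with an estimated correlation), and 7 of the 24 lists differed in camera, 0 with an estimated correlation (1 at an unadjusted p under 0.05). The ribosomal, heat shock and methylamine dehydrogenase lists differed by -0.48, 0.48 and -0.76 (camera adjusted p = 6.1e-14, 3.2e-07 and 4.9e-07, adjusted p = 0.54, 0.54 and 0.56 with an estimated correlation). The translation, TCA cycle and mobile element lists differed by -0.17, 0.29 and 0.06 (camera adjusted p = 0.0063, 0.013 and 0.031, adjusted p = 0.54, 0.56 and 0.54 with an estimated correlation).

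For the flagella and chemotaxis list, array design and scan day are argued against by a median difference of -0.10 between designs, and the dyes by a difference of -0.90 between replicates 2 and 1, which carry the same dyes. In the succinate channel the list's median signal differed by at most 0.12 in size between numbers (-0.12 on the first design, 0.07 on the second), while in the ethylamine channel it differed by -0.95 and -1.04. The pattern may therefore lie in the ethylamine samples. Whether cultures, growth stages or RNA extracts differed stays open, since the labels give none of these, and no biological explanation was tested.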
